A study of Capra hircus with 9 samples.

How the data were processed

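RNA of the rumen epithelium was sequenced in 9 libraries, 3 for each of 3 diets. The deposited files hold 1 value per gene and library in FPKM, fragments scaled by transcript length and by the mapped fragments, which the authors made with Bowtie 1.2.0 and Cufflinks 2.2.1 per the submitters' processing notes. No label states the unit in words, and it was read from the tool and the values. How the mapped fragments were counted for the scaling is not stated. The genome build and the strand of the reads are not given in the sources used here, and the RefSeq table of goat assembly ARS1.2 served for names and chromosomes only. Positions are those of the files, counted from 1. The FPKM of a library summed to 756030 in LC1 and to 903418 to 1051180 in the others.

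The files named 18383 genes, of which 16473 (89.6%) are in the RefSeq table. TPT1 and CD81 had more than 1 line per file, and these were summed. The MC and LC files held 18 to 21 lines whose names a spreadsheet had turned into dates, and the HC files held 0, so these lines were left out. The HC files also differed in a header word and held 11468 to 12038 empty lines against 0 in the others. Genes with no value in a file are not listed there. Of 11879 genes with at least 1 FPKM in at least 3 libraries, 211 were not listed in every library and were left out, which left 11668 tested. In the files 2491 genes share their locus with another gene, so their values are uncertain, and of the genes named here this holds for ATP1B1, BHLHE40, C1QC, CD3E, IDH3A, LIMS2, NEXN, TPM1 and ZNF750.

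Values as deposited were taken to log2(FPKM + 1), which understates changes of genes with low values. The diets were compared with limma 3.58.1 in R 4.3.3 in 1 fit of all libraries with a mean per diet, trend and robust moderation (residual degrees of freedom 6, median prior degrees of freedom 5.77), two-sided, with Benjamini-Hochberg adjustment per contrast and a threshold of 0.05, and the diets together with its F test. Lists of genes with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over all lists and contrasts. The tests, lists, alternatives and named genes were set before the data were examined, except where the text says otherwise. Named are the 10 largest rises and 10 largest falls per contrast among genes past the test whose libraries did not overlap, with a mean of at least 1 FPKM in the higher diet and a gene symbol, up to 4 members per list and contrast by adjusted p, and most of a panel of epithelial genes, of which SLC16A3 and TLR4 were not tested because they were low or not listed in every library. AQP3, BSG, C1QA, C1QB, C1QC, CCNE1, CD207, CD247, CD3D, CD3E, CDKN1B, CKM, CNFN, CSF1R, CTGF, CXCR2, DNAJA1, FCER1G, FXYD3, HSPA8, IRF7, JCHAIN, NKG7, PSMB8, RRM2, SMTN, TGM1, TNNT3 and ZNF750, most of them cell type markers, were chosen after their values were seen.

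Tested on simulated data with this spread, the fit called 0 genes where none was changed. With 200 genes changed it recovered 0% of genes changed by 0.5 log2, 76.5% to 84.5% at 1 and 95% to 97.5% at 2, and called 0, 1 to 13 and 5 to 14 unchanged genes. Alternatives changed the pseudocount, filter, scaling, moderation, library weights, threshold, set test and libraries used. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, tables read with pandas 2.3.3 and numpy 2.4.6, and the quality weights used statmod 1.5.0.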

Results

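RNA sequencing measured gene expression in the rumen epithelium, the lining of the largest forestomach, of goats aged 4 months. The 9 libraries fell into 3 diet groups, HC, MC and LC, with 3 libraries each. The series says only that the groups were fed 3 different types of concentrate diet, so the letters are used as the titles give them. The labels do not say that the libraries came from separate animals, so every p-value here measures only the spread between these samples. The files listed 15125 to 16719 genes per library, of which 10882 to 12011 reached 1 FPKM. They hold no read counts, so the depth of each library is unknown. The mitochondrial genome took 9.15% to 13.9% of the summed FPKM, with ND4 and ND4L not listed in the MC files, and cytosolic ribosomal protein genes took 26.9% in LC1 to 35.3% in HC2. Values below are mean FPKM ± SD over the 3 libraries of a diet (n = 3), log2 changes are given ± SE, and a list's median is that of its members' log2 changes. Beside a list's camera p stand adjusted p values of fits that changed its call, except fry and the replicate block. Leaving out 1 library, the smooth muscle marker mean as covariate and LC3 alone for LC (spread from HC and MC) were chosen after seeing the data.

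KRT5, the keratin of basal cells in stratified epithelia, stood at 3610.4 ± 792 FPKM in LC, 3979 ± 374 FPKM in MC and 3941 ± 946 FPKM in HC and passed the test in no contrast. Each diet's libraries stood together on the first principal components, which held 38.9% and 35.1% of the variance. Pearson correlation across genes, which are not independent replicates, ran from 0.965 to 0.993 within a diet and from 0.937 to 0.972 between diets.

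**Figure D1:**
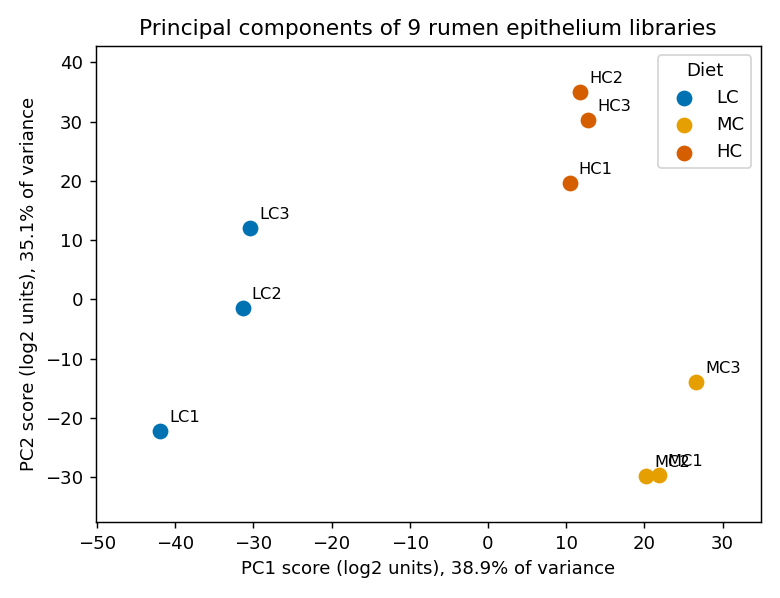
Scores of the 9 libraries on the first principal components of log2(FPKM + 1) over 11668 genes, with the share of variance on each axis (38.9% and 35.1%). Points are libraries and colours are diets, and each diet's libraries lie nearer to each other than to the rest.

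Of 11668 genes tested, 5274 (45.2%) differed among the 3 diets in the limma F test. Their mean was highest in LC for 2289 genes, in MC for 2149 and in HC for 836, and MC lay between the other diets for 1562. S100A8, which encodes a calcium-binding protein of neutrophils and inflamed epithelia, was high in LC (3288 ± 1089 FPKM) and far lower in MC (30.6 ± 13.3 FPKM) and HC (33.3 ± 12.8 FPKM). MAT2A, which makes the methyl donor S-adenosylmethionine, was high in MC (1279.5 ± 154 FPKM) against 183 ± 89.1 FPKM in LC and 149.7 ± 30.99 FPKM in HC. FUT6, a fucosyltransferase, was high in HC (47.3 ± 14.2 FPKM) against 5.04 ± 0.801 FPKM in LC and 2.17 ± 0.403 FPKM in MC. The deposited scale placed the median of all genes in HC lower, with a median log2 change of -0.10 in HC minus LC, -0.10 in HC minus MC and -0.0067 in MC minus LC, and changes involving HC are to be read against that shift.

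**Figure D2:**
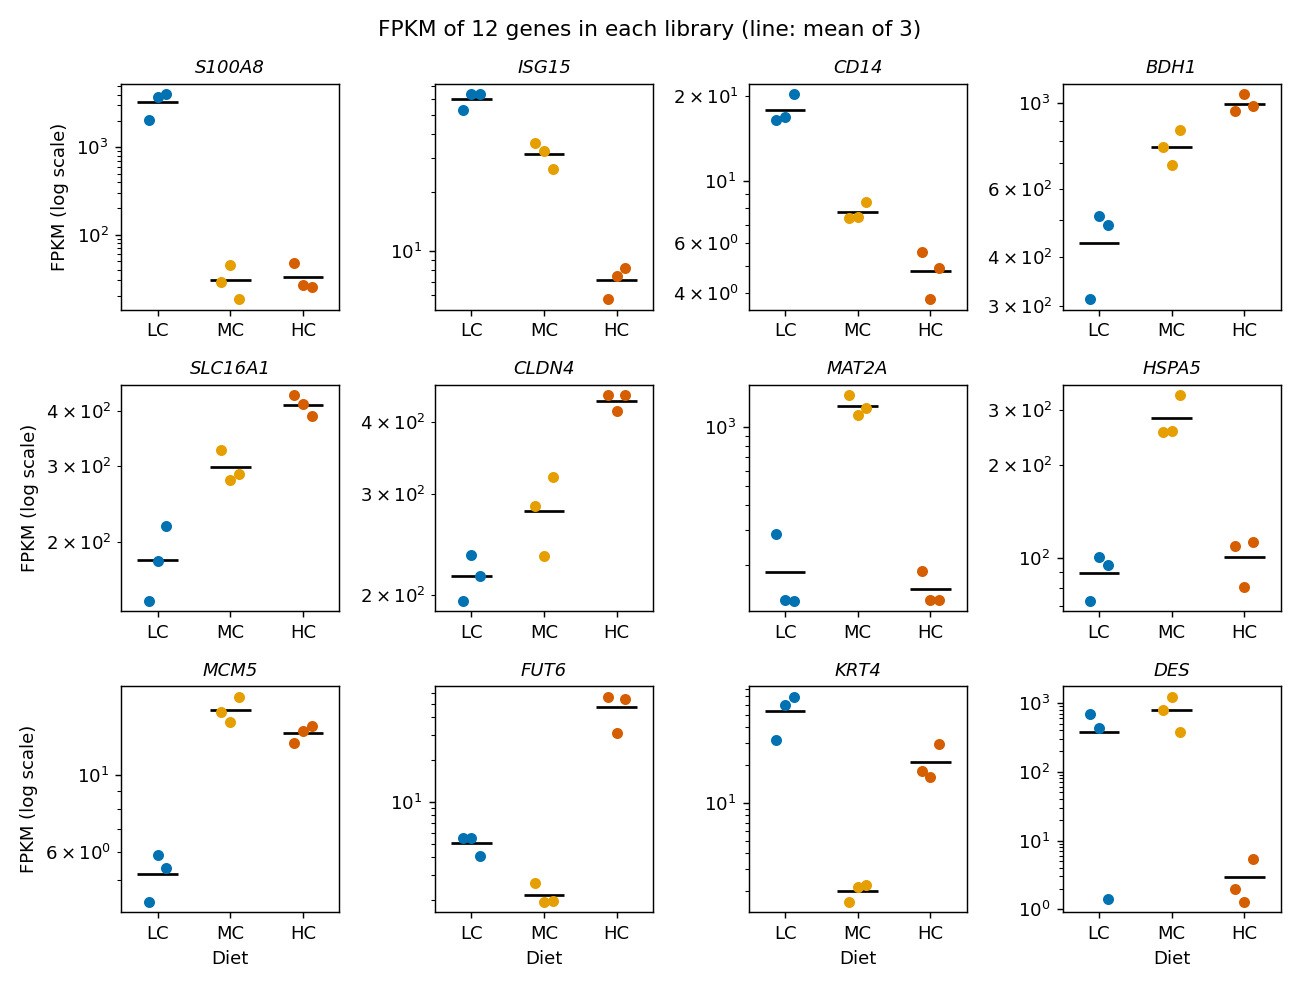
FPKM of 12 genes in each library, on a log axis, by diet. Points are libraries and lines are means of 3, and S100A8, ISG15 and CD14 were highest in LC, MAT2A and HSPA5 were highest in MC, and FUT6 was highest in HC, while DES differed within LC.

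HC minus LC compared the first pair of diets. S100A8, S100A12, 19 of 22 interferon response genes and 9 of 11 antigen presentation genes were lower in HC, and 8 of 18 genes of ketogenesis and short-chain fatty acid activation, 23 of 49 cell cycle and DNA replication genes, SLC16A1 and the urea transporter SLC14A1 were higher. S100A8 (chromosome 3, 16018873 to 16019899) fell from 3288 ± 1089 FPKM in LC to 33.3 ± 12.8 FPKM in HC (log2 change -6.58 ± 0.38, adjusted p = 7.78e-06), and its neighbour S100A12 (chromosome 3, 16038726 to 16040241) fell from 2247 ± 661 FPKM in LC to 31.1 ± 13.3 FPKM in HC (log2 change -6.16 ± 0.38, adjusted p = 1.04e-05). SLC16A1, a transporter of ketone bodies, lactate and short-chain fatty acids, rose from 182 ± 35.3 FPKM in LC to 413 ± 23.2 FPKM in HC (log2 change 1.197 ± 0.17, adjusted p = 4.55e-04). MX1, an interferon-induced GTPase, fell from 19.1 ± 1.07 FPKM in LC to 1.21 ± 0.175 FPKM in HC (log2 change -3.19 ± 0.12, adjusted p = 2.72e-08).

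In HC minus LC 2939 genes passed the test, 909 higher and 2030 lower in HC, and 579 of them changed by at least 1 on the log2 scale (192 higher, 387 lower). The 3 libraries of HC and of LC did not overlap for 40.6% of genes, against 10% by chance. The largest rises among named genes were FUT6 (2.96), the matricellular protein gene CYR61 (2.71), NCCRP1 (2.44), the gasdermin DFNA5 (2.43), the mitochondrial carrier SLC25A25 (2.24), the protease PRSS27 (2.18), DCLK3 (2.11), the organic cation exporter SLC47A2 (2.07) and the AP-1 subunit FOS (2.05), as log2 changes. The largest falls after S100A8 and S100A12 were the pantetheinase VNN2 (-3.96), the melanosome GTPase RAB38 (-3.51), MX1 (-3.19), GPNMB (-3.102), the ubiquitin-like ISG15 (-2.92), SPARCL1 (-2.67), arginase ARG1 (-2.44) and DUOXA2 (-2.38), and the SPARCL1 call was lost without HC replicate 2 (adjusted p = 0.131). The split rests on the scale: median-of-ratios scaling gave 1494 higher and 1329 lower. Without HC replicate 3 the count was 1769, and with LC3 alone it was 1379.

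In the list of ketogenesis and short-chain fatty acid activation, 8 of the 18 measured members rose, 2 fell and 8 did not pass the test (8 rises and 2 falls adjusted over the list alone). BDH1, which interconverts acetoacetate and 3-hydroxybutyrate, rose from 435 ± 108 FPKM in LC to 996 ± 53.9 FPKM in HC (log2 change 1.22 ± 0.20, adjusted p = 0.00115). OXCT1 (2.21 to 0.507 FPKM, log2 change -0.999) and ACSS1 (6.84 to 3.55 FPKM, log2 change -0.79), which use ketone bodies and acetate, fell, but both calls were lost after quantile normalization (adjusted p = 0.0734 and 0.0524) and without HC replicate 2 (adjusted p = 0.123 and 0.0535). As a set the list lay above other genes (median log2 0.42, camera adjusted p = 1.42e-04, adjusted p = 0.684 with an estimated correlation). The transport list for short-chain fatty acids, bicarbonate and protons had 6 rises among 19 measured members, 3 falls and 10 that did not pass the test (6 rises and 4 falls adjusted over the list alone), with carbonic anhydrase CA12 (216 to 509 FPKM, log2 change 1.23) and the SLC16A1 chaperone BSG (654 to 1146 FPKM, log2 change 0.82) among the rises (median log2 0.043, camera adjusted p = 0.0566, but 0.0433 without a filter, 0.0199 without HC2 (median 0.45), 0.0239 without LC1 (median 0.25), 0.0379 without HC3, 0.0289 with the covariate (median 0.30) and 0.0412 with LC3 alone (median 0.29)). The chloride-bicarbonate exchanger SLC26A3 (179 and 205 FPKM, adjusted p = 0.945) and the sodium-proton exchanger SLC9A3 (68.9 and 99.2 FPKM, adjusted p = 0.128) did not pass.

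In the list of ion, urea, ammonia and water transport, 7 of the 21 measured members rose, 4 fell and 10 did not pass the test (7 rises and 4 falls adjusted over the list alone), median log2 0.12, camera adjusted p = 0.0936, but 0.0371 without a filter. The urea transporter SLC14A1 rose from 47.9 ± 1.44 FPKM in LC to 139 ± 11.5 FPKM in HC (log2 change 1.52 ± 0.13, adjusted p = 2.09e-05). In the list of glucose and amino acid transport, 4 of the 20 measured members rose, 6 fell and 10 did not pass the test (6 rises and 8 falls adjusted over the list alone), median log2 -0.33, camera adjusted p = 0.655. SLC15A1, the apical peptide transporter, fell from 14.1 ± 1.47 FPKM in LC to 2.07 ± 0.294 FPKM in HC (log2 change -2.296 ± 0.13, adjusted p = 1.20e-06), and SLC5A1, the sodium-glucose cotransporter, fell from 31.2 ± 1.52 FPKM in LC to 8.66 ± 2.495 FPKM in HC (log2 change -1.77 ± 0.18, adjusted p = 5.26e-05). SLC1A4 (4.71 to 7.78 FPKM, log2 change 0.63) rose, and the glucose transporter SLC2A3 (2.58 to 0.361 FPKM, log2 change -1.35) fell.

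In the tricarboxylic acid cycle list 3 of 21 members rose, 0 fell and 18 did not pass (3 and 0 over the list alone). Their median was 0.25, with camera adjusted p = 4.41e-04, adjusted p = 0.726 with an estimated correlation, and 0.0888 after quantile normalization. Its rises were PCK2 (76.9 to 209.6 FPKM, log2 change 1.44), PC (0.716 to 3.35 FPKM, log2 change 1.32) and IDH1 (187 to 319 FPKM, log2 change 0.78), enzymes that supply or leave the cycle. In the nuclear oxidative phosphorylation list 1 of 32 members rose, 0 fell and 31 did not pass (0 and 0 over the list alone). Their median was 0.11, with camera adjusted p = 0.0238, adjusted p = 0.7897 with an estimated correlation, and 0.751 after quantile normalization, 0.9197 without LC1 (median -0.084), 0.3399 with the covariate (median -0.054) and 0.872 with LC3 alone (median -0.12). In the glycolysis and lactate list 0 of 19 members rose, 3 fell and 16 did not pass (0 and 2 over the list alone). Their median was -0.17, with camera adjusted p = 0.317, but 0.0187 after quantile normalization. In the cholesterol biosynthesis list 3 of 22 members rose, 3 fell and 16 did not pass (3 and 3 over the list alone). Their median was 0.042, with camera adjusted p = 0.205. INSIG1 (18.7 to 42.6 FPKM, log2 change 1.11), which retains the sterol sensor, rose. In the fatty acid synthesis and storage list 2 of 21 members rose, 3 fell and 16 did not pass (2 and 3 over the list alone). Their median was -0.19, with camera adjusted p = 0.958. In the fatty acid oxidation and PPAR target list 5 of 30 members rose, 5 fell and 20 did not pass (5 and 8 over the list alone). Their median was -0.049, the mean -0.064, direction of the set test up, with camera adjusted p = 0.564. In that list ACAA1 (153 to 319 FPKM, log2 change 1.09) rose and CPT1A (20.2 to 11.5 FPKM, log2 change -0.76) fell.

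In the list of cell cycle and DNA replication, 23 of the 49 measured members rose, 1 fell and 25 did not pass the test (26 rises and 1 fall adjusted over the list alone). MCM5, a subunit of the replicative helicase, rose from 5.205 ± 0.808 FPKM in LC to 13.2 ± 0.748 FPKM in HC (log2 change 1.2003 ± 0.13, adjusted p = 6.17e-05), and CDT1 (1.32 to 4.2995 FPKM, log2 change 1.18), MCM2 (4.58 to 10.1 FPKM, log2 change 1.006) and CCNE1 (0.879 to 2.63 FPKM, log2 change 0.93) also rose. The list lay above other genes (median log2 0.46, camera adjusted p = 3.16e-12, adjusted p = 0.122 with an estimated correlation), while the proliferation marker MKI67 (0.924 and 1.74 FPKM, adjusted p = 0.0743) did not pass. Cytosolic ribosomal proteins lay higher as a set with 0 of 68 members past limma's test, 10 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median log2 0.31, camera adjusted p = 1.12e-08, adjusted p = 0.778 with an estimated correlation, and 0.1201 after quantile normalization).

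CLDN4, a tight junction claudin, rose from 216 ± 19.7 FPKM in LC to 435 ± 16.1 FPKM in HC (log2 change 1.014 ± 0.16, adjusted p = 8.88e-04), and CLDN23 fell from 7.22 ± 1.53 FPKM in LC to 1.802 ± 0.312 FPKM in HC (log2 change -1.54 ± 0.15, adjusted p = 4.48e-05). The junction proteins CLDN1 (58.6 and 53.5 FPKM, adjusted p = 0.6003), OCLN (42.1 and 38.04 FPKM, adjusted p = 0.46003) and TJP1 (16.3 and 15.6 FPKM, adjusted p = 0.773) did not pass. In the tight junction list 4 of 23 members rose, 1 fell and 18 did not pass (4 and 1 over the list alone). Their median was -0.095, the mean -0.088, direction of the set test up, with camera adjusted p = 0.3995. In the desmosome and adherens junction list 0 of 24 members rose, 6 fell and 18 did not pass (0 and 6 over the list alone). Their median was -0.19, with camera adjusted p = 0.156, but 0.00705 after quantile normalization and 0.0326 with the covariate (median -0.31). Desmoglein DSG3 (369 to 179.98 FPKM, log2 change -1.015) was among the falls. In the basal epithelial layer list 0 of 16 members rose, 2 fell and 14 did not pass (0 and 1 over the list alone). Their median was -0.31, with camera adjusted p = 0.453. It held the integrin ITGA6 (25.8 to 14.8 FPKM, log2 change -0.75). In the cornified and differentiated layer list 7 of 28 members rose, 6 fell and 15 did not pass (7 and 6 over the list alone). Their median was 0.081, with camera adjusted p = 0.156, but 0.0199 without HC2 (median 0.23). KRT80 (35.7 to 95.9 FPKM, log2 change 1.37) and ALOX12B (2.44 to 6.57 FPKM, log2 change 1.11) rose there, and the transglutaminase TGM3 (536 to 268 FPKM, log2 change -0.99) and the transcription factor ZNF750 (34.7 to 18.5 FPKM, log2 change -0.87) fell.

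In the interferon response list, 0 of the 22 measured members rose, 19 fell and 3 did not pass the test (0 rises and 21 falls adjusted over the list alone). ISG15 fell from 60.03 ± 6.48 FPKM in LC to 7.12 ± 1.31 FPKM in HC (log2 change -2.92 ± 0.16, adjusted p = 6.54e-07), and PARP9 (10.97 to 2.03 FPKM, log2 change -1.98), IRF9 (18.99 to 5.22 FPKM, log2 change -1.695) and IRF7 (18.7 to 6.29 FPKM, log2 change -1.43) also fell (median log2 -0.95, camera adjusted p = 1.43e-10, adjusted p = 0.0417 with an estimated correlation). In the antigen presentation list, 1 of the 11 measured members rose, 9 fell and 1 did not pass the test (1 rise and 10 falls adjusted over the list alone). The immunoproteasome subunit PSMB8 (12.2 to 3.17 FPKM, log2 change -1.68), the peptide transporter TAP2 (6.89 to 1.42 FPKM, log2 change -1.702) and the class II chaperone CD74 (111 to 41.1 FPKM, log2 change -1.43) fell, and PSMB10 (27.8 to 63.3 FPKM, log2 change 1.19) rose (median log2 -1.06, camera adjusted p = 2.49e-04, adjusted p = 0.108 with an estimated correlation). In the Toll-like receptor and NF-kB list 2 of 35 members rose, 12 fell and 21 did not pass (2 and 13 over the list alone). Their median was -0.12, with camera adjusted p = 0.218. TLR2, a receptor for bacterial lipoproteins, fell from 20.98 ± 2.07 FPKM in LC to 5.61 ± 1.28 FPKM in HC (log2 change -1.75 ± 0.15, adjusted p = 1.41e-05), its coreceptor CD14 (17.9 to 4.78 FPKM, log2 change -1.72) fell, and FOS (9.65 to 42.5 FPKM, log2 change 2.05) rose. In the cytokine and chemokine list 1 of 27 members rose, 10 fell and 16 did not pass (1 and 10 over the list alone). Their median was -0.17, with camera adjusted p = 0.143. CSF1 (6.45 to 1.42 FPKM, log2 change -1.62) and CCL5 (5.16 to 1.31 FPKM, log2 change -1.399) fell, as did IL1B from 1.51 ± 0.341 FPKM in LC to 0.332 ± 0.126 FPKM in HC (log2 change -0.91 ± 0.16, adjusted p = 0.00198).

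In the epithelial host defence list 1 of 13 members rose, 6 fell and 6 did not pass (1 and 7 over the list alone). Their median was -0.67, with camera adjusted p = 0.02104, adjusted p = 0.425 with an estimated correlation. Beside S100A8 and S100A12, DUOXA2 (14.6 to 2.17 FPKM, log2 change -2.38) and the peptidoglycan-binding PGLYRP4 (14.2 to 3.64 FPKM, log2 change -1.71) fell, and the nitric oxide synthase NOS2 (6.55 to 24.7 FPKM, log2 change 1.71) rose. In the apoptosis list 2 of 29 members rose, 8 fell and 19 did not pass (2 and 10 over the list alone). Their median was -0.079, with camera adjusted p = 0.448. Caspase CASP1 (6.36 to 1.796 FPKM, log2 change -1.38) fell. In the growth factor and IGF list 4 of 31 members rose, 10 fell and 17 did not pass (5 and 10 over the list alone). Their median was -0.29, with camera adjusted p = 0.827. AREG (2.03 to 7.93 FPKM, log2 change 1.53) and CTGF (0.665 to 3.098 FPKM, log2 change 1.29) rose, TGFB1 (14.4 to 6.59 FPKM, log2 change -1.02) and the receptor MET (4.09 to 1.29 FPKM, log2 change -1.15) fell, and IGFBP5 (24.4 and 34.6 FPKM, adjusted p = 0.0624) did not pass.

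In the oxidative stress, heat shock and unfolded protein list 8 of 49 members rose, 6 fell and 35 did not pass (9 and 6 over the list alone). Their median was 0.13, with camera adjusted p = 0.02104, adjusted p = 0.778 with an estimated correlation, and 0.474 after quantile normalization, 0.0561 without LC1 (median 0.032), 0.0652 with the covariate (median 0.048) and 0.0711 with LC3 alone (median 0.082). ATF3 (1.13 to 2.67 FPKM, log2 change 0.78) rose, and GPX2 (17.8 to 10.04 FPKM, log2 change -0.76) fell. In the xenobiotic and retinoid metabolism list 9 of 26 members rose, 4 fell and 13 did not pass (9 and 4 over the list alone). Their median was 0.11, with camera adjusted p = 0.0369, adjusted p = 0.425 with an estimated correlation, and 0.159 after quantile normalization and 0.0538 without HC1. EPHX2 (6.88 to 15.4 FPKM, log2 change 1.07) rose there, and DHRS3 (26.7 to 14.4 FPKM, log2 change -0.85) fell. In the circadian clock list 1 of 18 members rose, 5 fell and 12 did not pass (3 and 6 over the list alone). Their median was -0.093, with camera adjusted p = 0.781. BHLHE40 (64.4 to 30.9 FPKM, log2 change -1.03), which shares its locus with ITPR1, was among its falls. The list of fatty acid and metabolite receptors had 1 measured member, FFAR4 (10.9 to 5.499 FPKM, log2 change -0.88), which fell before and after being adjusted over the list alone.

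Markers of other cell types differed between libraries. The mean log2 value of the 9 smooth muscle markers was 7.18, 6.32 and 2.27 in the LC libraries and 3.07, 3.25 and 3.49 in the HC libraries, and 0 passed limma's test, 1 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median log2 -2.26, camera adjusted p = 0.291, but 3.16e-06 without LC3 and 9.94e-04 with LC3 alone (median 0.95)). In the fibroblast list 0 of 10 members rose, 2 fell and 8 did not pass (0 and 2 over the list alone). Their median was -0.86, with camera adjusted p = 0.0438, adjusted p = 0.778 with an estimated correlation, and 0.0543 with a pseudocount of 0.1, 0.0655 without a filter, 0.275 without LC1, 0.153 without HC2, 0.05603 without LC2, 0.0542 without HC3, 0.0536 without MC2, 0.401 with the covariate (median -0.45) and 0.93004 with LC3 alone (median -0.31). In the endothelium list 0 of 9 members rose, 1 fell and 8 did not pass (0 and 3 over the list alone). Their median was -0.94, with camera adjusted p = 0.0846, but 0.04997 after quantile normalization, 0.00449 without LC3 and 0.0291 without HC1. In the extracellular matrix list 1 of 26 members rose, 4 fell and 21 did not pass (1 and 4 over the list alone). Their median was -0.63, with camera adjusted p = 0.0396, adjusted p = 0.778 with an estimated correlation, and 0.0543 with a pseudocount of 0.1, 0.0568 without a filter, 0.438 without LC1 (median -0.33), 0.0772 without HC2, 0.0692 without HC3, 0.797 with the covariate (median -0.15) and 0.675 with LC3 alone (median -0.080). These 3 lists varied with the smooth muscle markers inside LC: their means in LC1, LC2 and LC3 were 5.22, 4.59 and 4.02 for fibroblast genes, 3.29, 2.56 and 2.01 for endothelium, and 3.83, 3.23 and 2.74 for extracellular matrix. SPARCL1 was 32.04, 14.3 and 4.53 FPKM in the LC libraries and so varied with them.

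In the T and NK cell list 1 of 6 members rose, 5 fell and 0 did not pass (1 and 5 over the list alone). Their median was -1.06, with camera adjusted p = 0.0238, adjusted p = 0.293 with an estimated correlation, and 0.0543 with a pseudocount of 0.1 (median -2.24). The T cell receptor chains CD3E (3.65 to 0.574 FPKM, log2 change -1.58) and CD3D (1.68 to 0.236 FPKM, log2 change -1.11) fell, and the granule protein NKG7 (2.91 to 11.8 FPKM, log2 change 1.68) rose. In the macrophage and dendritic cell list 0 of 9 members rose, 4 fell and 5 did not pass (0 and 5 over the list alone). Their median was -0.50, with camera adjusted p = 0.0205, adjusted p = 0.425 with an estimated correlation. The Langerhans cell lectin CD207 (3.72 to 0.252 FPKM, log2 change -1.91) and CSF1R (6.48 to 2.35 FPKM, log2 change -1.15) fell. The B and plasma cell list had 1 measured member, JCHAIN (2.92 to 1.32 FPKM, log2 change -0.78), which fell, but not after quantile normalization (adjusted p = 0.0893), and the neutrophil list had 1, CXCR2 (1.897 and 1.16 FPKM, adjusted p = 0.05797), which fell adjusted over the list alone. Of the striated muscle list 2 members were measured, CKM (4.81 and 5.48 FPKM, adjusted p = 0.368) and TNNT3 (182 and 166 FPKM, adjusted p = 0.807), with 0 calls adjusted over the list alone. No member of the lists for mast cells, erythrocytes, nerve and glia, adipocytes, melanocytes or liver and gland was tested, since they were low, not listed in every library or in no file. The means of the T and NK cell markers in LC1, LC2 and LC3 were 1.83, 1.81 and 1.79, against 1.11, 1.14 and 1.05 in the HC libraries, so they moved with the interferon, antigen presentation and cytokine lists between these diets and not with smooth muscle.

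**Figure D3:**
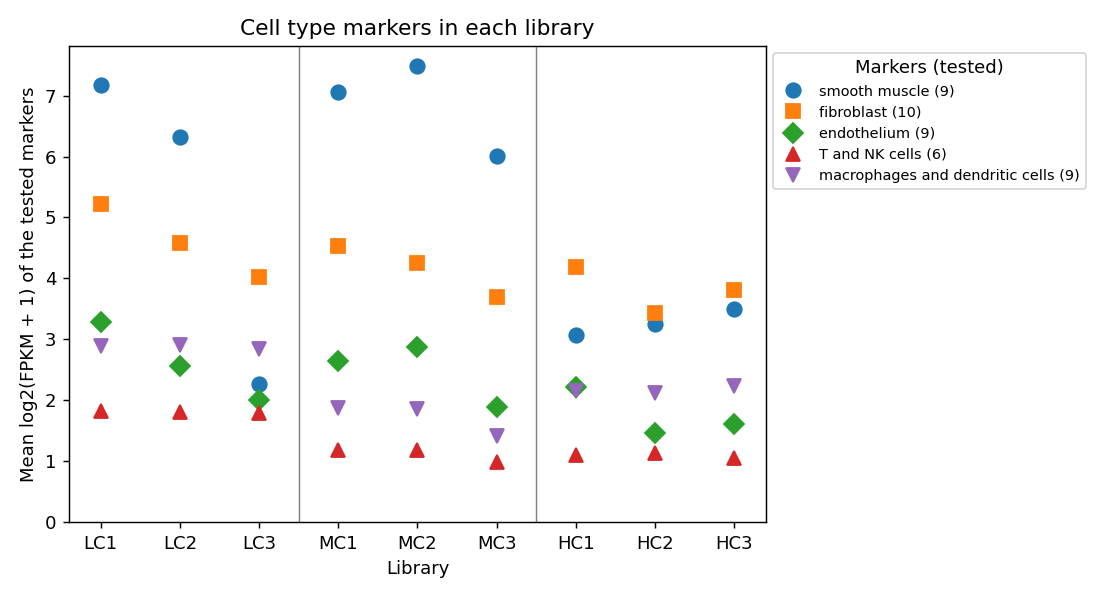
Mean log2(FPKM + 1) of the tested markers of 5 cell types in each library, with the number of markers in the legend and points for libraries, grouped by diet. Smooth muscle markers stood at 7.18 in LC1 and 2.27 in LC3, whereas T and NK cell markers were nearly level within each diet.

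MC minus LC put a further diet beside LC. MAT2A, ODC1, HSPA5 and 38 of 49 cell cycle and DNA replication genes were higher in MC, and S100A8, S100A12, KRT4, 8 of 11 antigen presentation genes and 8 of 9 macrophage and dendritic cell markers were lower. MAT2A (chromosome 11, 48854892 to 48861358) rose from 183 ± 89.1 FPKM in LC to 1279.5 ± 154 FPKM in MC (log2 change 2.895 ± 0.28, adjusted p = 3.05e-05), and ODC1, the first enzyme of polyamine synthesis, rose from 3.74 ± 0.489 FPKM in LC to 21.7 ± 8.03 FPKM in MC (log2 change 2.21 ± 0.24, adjusted p = 9.14e-05). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 89.2 ± 14.6 FPKM in LC to 282 ± 45.5 FPKM in MC (log2 change 1.65 ± 0.19, adjusted p = 6.90e-05). S100A8 fell from 3288 ± 1089 FPKM in LC to 30.6 ± 13.3 FPKM in MC (log2 change -6.73 ± 0.38, adjusted p = 4.74e-06) and S100A12 fell from 2247 ± 661 FPKM in LC to 31.03 ± 12.2 FPKM in MC (log2 change -6.17 ± 0.38, adjusted p = 7.38e-06). KRT4 (chromosome 5, 26374429 to 26381614), a keratin of differentiated mucosal epithelium, fell from 53.8 ± 19.9 FPKM in LC to 2.03 ± 0.331 FPKM in MC (log2 change -4.11 ± 0.30, adjusted p = 1.51e-05).

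In MC minus LC 3894 genes passed the test, 1896 higher and 1998 lower in MC, and 756 changed by at least 1 on the log2 scale (325 higher, 431 lower). The libraries did not overlap for 47.1% of genes, against 10% by chance. Beside MAT2A and ODC1 the largest rises were the cytokine receptor TNFRSF12A (2.72), PLEKHG6 (2.64), uridine phosphorylase UPP1 (2.598), SLC47A2 (2.33), SERPINB11 (2.29), DFNA5 (2.27), the thioesterase ACOT7 (2.25) and the lysolipid transporter MFSD2A (2.21), as log2 changes. The largest falls beside the S100 genes and KRT4 were GPNMB (-5.41), VNN2 (-3.75), the kallikrein KLK12 (-3.72), RAB38 (-3.36), ARG1 (-3.17), MX1 (-2.77) and the carnitine synthesis enzyme BBOX1 (-2.72). With LC3 alone the count was 2322.

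In the list of cell cycle and DNA replication, 38 of the 49 measured members rose, 3 fell and 8 did not pass the test (40 rises and 5 falls adjusted over the list alone). PCNA, the replication clamp, rose from 11.8 ± 1.94 FPKM in LC to 34.6 ± 4.56 FPKM in MC (log2 change 1.48 ± 0.15, adjusted p = 4.00e-05), and MCM5 (5.205 to 15.4 FPKM, log2 change 1.41), TYMS (2.7995 to 9.36 FPKM, log2 change 1.45) and RRM2 (1.66 to 6.21 FPKM, log2 change 1.44) rose with it (median log2 0.70, camera adjusted p = 2.48e-12, adjusted p = 0.122 with an estimated correlation). CDKN1B (35.4 to 22.6 FPKM, log2 change -0.62), an inhibitor of the cycle, fell, and MKI67 (0.924 and 1.75 FPKM, adjusted p = 0.0552) did not pass. In the oxidative stress, heat shock and unfolded protein list 24 of 49 members rose, 5 fell and 20 did not pass (25 and 6 over the list alone). Their median was 0.39, with camera adjusted p = 3.40e-04, adjusted p = 0.645 with an estimated correlation. HSPA8 (301 to 762 FPKM, log2 change 1.35), DNAJA1 (43.8 to 105 FPKM, log2 change 1.26) and the quinone reductase NQO1 (22.9 to 87.1 FPKM, log2 change 1.94) rose, and HMOX1 (44.1 to 14.9 FPKM, log2 change -1.501) fell. In the cholesterol biosynthesis list 10 of 22 members rose, 1 fell and 11 did not pass (12 and 1 over the list alone). Their median was 0.40, with camera adjusted p = 0.0155, adjusted p = 0.778 with an estimated correlation, and 0.0528 without LC1 and 0.222 with LC3 alone (median 0.23). The sterol dehydrogenase NSDHL (21.1 to 35.2 FPKM, log2 change 0.71) rose.

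In the ketogenesis and short-chain fatty acid activation list 3 of 18 members rose, 0 fell and 15 did not pass (3 and 0 over the list alone). Their median was 0.23, with camera adjusted p = 0.0538, but 0.0207 without a filter, 0.0178 without LC3, 0.0251 without LC2 and 0.0134 with the covariate (median 0.35). Among its rises was BDH1 (435 to 771 FPKM, log2 change 0.85). In the short-chain fatty acid, bicarbonate and proton transport list 5 of 19 members rose, 2 fell and 12 did not pass (6 and 2 over the list alone). Their median was 0.15, with camera adjusted p = 0.349. SLC16A1 rose from 182 ± 35.3 FPKM in LC to 297 ± 25.2 FPKM in MC (log2 change 0.72 ± 0.17, adjusted p = 0.00618). SLC26A2 (53.7 to 24.002 FPKM, log2 change -1.13) fell, and the exchangers SLC26A3 and SLC9A3 did not pass. In the ion, urea, ammonia and water transport list 7 of 21 members rose, 3 fell and 11 did not pass (7 and 3 over the list alone). Their median was 0.086, with camera adjusted p = 0.156. SLC14A1 (47.9 to 141 FPKM, log2 change 1.53) and AQP3 (92.9 to 183 FPKM, log2 change 0.97) rose, and the sodium pump regulator FXYD3 (1628 to 829 FPKM, log2 change -0.96) fell. In the glucose and amino acid transport list 4 of 20 members rose, 6 fell and 10 did not pass (6 and 6 over the list alone). Their median was -0.089, with camera adjusted p = 0.462. SLC7A5 (1.57 to 7.31 FPKM, log2 change 1.68) and SLC7A1 (2.59 to 6.16 FPKM, log2 change 0.99), which carry large neutral and cationic amino acids, rose, and SLC15A1 (14.1 to 1.58 FPKM, log2 change -2.55) and SLC5A1 (31.2 to 16.8 FPKM, log2 change -0.86) fell.

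In the tricarboxylic acid cycle list 3 of 21 members rose, 0 fell and 18 did not pass (3 and 0 over the list alone). Their median was 0.13, with camera adjusted p = 0.274. IDH3A (13.4 to 33.3 FPKM, log2 change 1.25) had the largest rise there, though it shares its locus with ACSBG1. In the nuclear oxidative phosphorylation list 2 of 32 members rose, 1 fell and 29 did not pass (0 and 0 over the list alone). Their median was -0.053, with camera adjusted p = 0.897, but 0.02704 without LC1 (median -0.23). In the glycolysis and lactate list 0 of 19 members rose, 3 fell and 16 did not pass (0 and 1 over the list alone). Their median was -0.29, with camera adjusted p = 0.0437, adjusted p = 0.725 with an estimated correlation, and 0.0531 with a pseudocount of 0.1, 0.0936 without LC2, 0.0585 without MC2, 0.0524 without MC3, 0.0517 without LC3, 0.062997 with the covariate and 0.0615 with LC3 alone. PDK1 (18.5 to 9.45 FPKM, log2 change -0.90), the kinase that inhibits pyruvate dehydrogenase, was among its falls. In the fatty acid synthesis and storage list 2 of 21 members rose, 4 fell and 15 did not pass (2 and 4 over the list alone). Their median was 0.18, the mean -0.0039, direction of the set test up, with camera adjusted p = 0.824. The desaturase SCD (2.77 to 7.99 FPKM, log2 change 1.23) rose and PLIN2 (129 to 62.3 FPKM, log2 change -1.03) fell. In the fatty acid oxidation and PPAR target list 3 of 30 members rose, 9 fell and 18 did not pass (3 and 9 over the list alone). Their median was -0.13, with camera adjusted p = 0.386. The binding protein FABP5 (699 to 1740 FPKM, log2 change 1.35) rose and ACAA1 (153 to 77.2 FPKM, log2 change -0.95) fell.

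In the cornified and differentiated layer list 4 of 28 members rose, 7 fell and 17 did not pass (4 and 8 over the list alone). Their median was 0.050, the mean -0.27, direction of the set test down, with camera adjusted p = 0.774. Beside KRT4 the falls held KLK12 (74.3 to 4.703 FPKM, log2 change -3.72) and CNFN (37.2 to 9.34 FPKM, log2 change -1.88), and the rises held KRT80 (35.7 to 87.1 FPKM, log2 change 1.26) and the transglutaminase TGM1 (159 to 336 FPKM, log2 change 1.08). In the tight junction list 5 of 23 members rose, 1 fell and 17 did not pass (5 and 1 over the list alone). Their median was 0.098, with camera adjusted p = 0.349. CLDN7 (2.23 to 5.36 FPKM, log2 change 0.99) rose and CLDN23 (7.22 to 3.11 FPKM, log2 change -0.99) fell. CLDN4 (216 and 280.4 FPKM, adjusted p = 0.0906), CLDN1, OCLN and TJP1 did not pass. In the desmosome and adherens junction list 1 of 24 members rose, 6 fell and 17 did not pass (1 and 6 over the list alone). Their median was -0.13, with camera adjusted p = 0.156, but 0.0492 after quantile normalization and 0.0343 without MC3 (median -0.27). GJB6 (3.203 to 1.07 FPKM, log2 change -1.02) fell. In the basal epithelial layer list 1 of 16 members rose, 2 fell and 13 did not pass (1 and 2 over the list alone). Their median was -0.25, with camera adjusted p = 0.608. ITGA3 (4.33 to 10.5 FPKM, log2 change 1.11) rose, and COL17A1 (197 to 115 FPKM, log2 change -0.78) fell.

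In the interferon response list 0 of 22 members rose, 14 fell and 8 did not pass (0 and 15 over the list alone). Their median was -0.61, with camera adjusted p = 1.28e-07, adjusted p = 0.0534 with an estimated correlation. MX1 (19.1 to 1.95 FPKM, log2 change -2.77) and DHX58 (18.7 to 6.49 FPKM, log2 change -1.39) fell. In the antigen presentation list 0 of 11 members rose, 8 fell and 3 did not pass (0 and 9 over the list alone). Their median was -1.09, with camera adjusted p = 2.74e-05, adjusted p = 0.0806 with an estimated correlation. CD74 fell from 111 ± 8.25 FPKM in LC to 29.6 ± 0.251 FPKM in MC (log2 change -1.87 ± 0.14, adjusted p = 5.44e-06), and TAP1 (12.7 to 2.98 FPKM, log2 change -1.78) and PSMB8 (12.2 to 2.89 FPKM, log2 change -1.83) fell. In the Toll-like receptor and NF-kB list 5 of 35 members rose, 8 fell and 22 did not pass (6 and 8 over the list alone). Their median was -0.057, with camera adjusted p = 0.655. TLR2 fell from 20.98 ± 2.07 FPKM in LC to 9.22 ± 0.911 FPKM in MC (log2 change -1.105 ± 0.15, adjusted p = 2.07e-04) and FOS (9.65 to 16.7 FPKM, log2 change 0.75) rose. In the cytokine and chemokine list 2 of 27 members rose, 10 fell and 15 did not pass (2 and 10 over the list alone). Their median was -0.24, with camera adjusted p = 0.0238, adjusted p = 0.293 with an estimated correlation. CCL5 (5.16 to 0.521 FPKM, log2 change -2.04), IL2RG (3.76 to 0.542 FPKM, log2 change -1.61) and IL1B (1.51 to 0.251 FPKM, log2 change -0.997) fell, and IL17RC (26.95 to 43.9 FPKM, log2 change 0.68) rose.

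In the epithelial host defence list 3 of 13 members rose, 5 fell and 5 did not pass (3 and 5 over the list alone). Their median was -0.091, with camera adjusted p = 0.211. S100A14 (61.3 to 115 FPKM, log2 change 0.98) rose while S100A8 and S100A12 fell. In the apoptosis list 2 of 29 members rose, 8 fell and 19 did not pass (2 and 10 over the list alone). Their median was -0.19, with camera adjusted p = 0.156. CASP1 (6.36 to 1.17 FPKM, log2 change -1.75) fell. In the growth factor and IGF list 6 of 31 members rose, 10 fell and 15 did not pass (6 and 11 over the list alone). Their median was -0.25, with camera adjusted p = 0.317. The epidermal growth factor receptor ligands AREG (2.03 to 12.8 FPKM, log2 change 2.19) and EREG (0.582 to 4.79 FPKM, log2 change 1.88) rose, and FGFR2 (18.4 to 7.08 FPKM, log2 change -1.26) and IGFBP5 (24.4 to 11.8 FPKM, log2 change -0.97) fell. In the xenobiotic and retinoid metabolism list 6 of 26 members rose, 6 fell and 14 did not pass (6 and 6 over the list alone). Their median was 0.10, the mean -0.0036, direction of the set test down, with camera adjusted p = 0.975. EPHX2 (6.88 to 31.3 FPKM, log2 change 2.06) rose, and DHRS3 (26.7 to 8.198 FPKM, log2 change -1.58) fell. In the circadian clock list 2 of 18 members rose, 9 fell and 7 did not pass (2 and 9 over the list alone). Their median was -0.36, with camera adjusted p = 0.0846. CRY1 (1.05 to 3.903 FPKM, log2 change 1.25) rose, and DBP (35.7 to 17.5 FPKM, log2 change -1.004) fell.

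In the macrophage and dendritic cell list 0 of 9 members rose, 8 fell and 1 did not pass (0 and 9 over the list alone). Their median was -1.28, with camera adjusted p = 2.74e-05, adjusted p = 0.171 with an estimated correlation. The complement genes C1QA (12.1 to 4.32 FPKM, log2 change -1.36) and C1QB (9.73 to 3.35 FPKM, log2 change -1.35) and the receptor CSF1R (6.48 to 2.05 FPKM, log2 change -1.29) fell. In the T and NK cell list 1 of 6 members rose, 4 fell and 1 did not pass (1 and 5 over the list alone). Their median was -1.11, with camera adjusted p = 0.0238, adjusted p = 0.293 with an estimated correlation. CD3E (3.65 to 0.605 FPKM, log2 change -1.56) fell and NKG7 (2.91 to 8.504 FPKM, log2 change 1.28) rose. The T and NK cell markers averaged 1.18, 1.19 and 0.99 in the MC libraries, so these and the macrophage markers moved with the interferon, antigen presentation and cytokine lists between MC and LC. The smooth muscle markers averaged 7.06, 7.49 and 6.003 in the MC libraries, and 0 passed limma's test, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median log2 1.82, camera adjusted p = 0.1399, but 0.0174 without LC1 (median 2.82), 0.0411 without MC3 and 2.11e-09 with LC3 alone (median 4.74)). In the fibroblast list 0 of 10 members passed limma's test and 3 had an unadjusted p under 0.05 (0 rises and 0 falls adjusted over the list alone). Their median was -0.48, with camera adjusted p = 0.224, but 0.02196 without LC3 (median -0.79) and 0.00905 with the covariate (median -0.87). In the endothelium list 0 of 9 members rose, 1 fell and 8 did not pass (0 and 1 over the list alone). Their median was -0.066, with camera adjusted p = 0.6698. In the extracellular matrix list 1 of 26 members rose, 5 fell and 20 did not pass (1 and 5 over the list alone). Their median was -0.37, with camera adjusted p = 0.0538, but 0.04997 after quantile normalization, 3.31e-04 without LC3 (median -0.65), 0.0163 without MC2, 0.0254 without MC1 and 1.22e-05 with the covariate (median -0.74). MMP14 (75.001 to 26.6 FPKM, log2 change -1.47) fell and MMP9 (1.38 to 4.93 FPKM, log2 change 1.34) rose, and these 3 lists varied with smooth muscle inside LC as given for HC minus LC. With LC3 alone their medians turned positive, to 0.28 for extracellular matrix, 0.061 for fibroblast and 0.61 for endothelium.

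Of the single measured members of the small lists, FFAR4 (10.9 and 14.8 FPKM, adjusted p = 0.0614) and CXCR2 (1.897 and 1.67 FPKM, adjusted p = 0.549) did not pass, and JCHAIN (2.92 to 1.29 FPKM, log2 change -0.78) fell. Over a list of 1 member limma's p stays unadjusted, and there FFAR4 was under 0.05 and CXCR2 was not. Of striated muscle, CKM (4.81 to 3.35 FPKM, log2 change -0.40) fell, but not without LC replicate 3 (adjusted p = 0.146), and TNNT3 (182 and 98.4 FPKM, adjusted p = 0.0757) did not pass, and 2 fell adjusted over the list alone. Ribosomal proteins did not pass as a set, with 0 of 68 past limma's test, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median log2 -0.057, camera adjusted p = 0.583, but 8.67e-06 without LC1 (median -0.28) and 1.33e-04 with LC3 alone (median -0.27)).

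HC minus MC compared the remaining pair of diets. FUT6, CYR61, KRT4, KLK12 and KLK14 were higher in HC, and MAT2A, HSPA5 and 16 of 49 cell cycle and DNA replication genes were lower. FUT6 (chromosome 7, 14952990 to 14955773) rose from 2.17 ± 0.403 FPKM in MC to 47.3 ± 14.2 FPKM in HC (log2 change 3.88 ± 0.21, adjusted p = 2.83e-06), and CYR61 (chromosome 3, 55152234 to 55154548), a matricellular protein, rose from 2.4996 ± 1.502 FPKM in MC to 38.5 ± 8.21 FPKM in HC (log2 change 3.59 ± 0.36, adjusted p = 4.04e-04). KRT4 rose from 2.03 ± 0.331 FPKM in MC to 21.1 ± 7.09 FPKM in HC (log2 change 2.83 ± 0.30, adjusted p = 3.17e-04) and KLK12, a secreted serine protease, rose from 4.703 ± 1.25 FPKM in MC to 44.5 ± 11.04 FPKM in HC (log2 change 2.99 ± 0.23, adjusted p = 2.68e-05). MAT2A fell from 1279.5 ± 154 FPKM in MC to 149.7 ± 30.99 FPKM in HC (log2 change -3.099 ± 0.28, adjusted p = 7.39e-05). DES (chromosome 2, 106737541 to 106744377), the intermediate filament protein of muscle, fell from 799.9 ± 425 FPKM in MC to 2.905 ± 2.25 FPKM in HC (log2 change -7.67 ± 2.14, adjusted p = 0.0445), a call that was lost without MC replicate 1 (adjusted p = 0.121).

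In HC minus MC 2917 genes passed the test, 933 higher and 1984 lower in HC, and 394 changed by at least 1 on the log2 scale (154 higher, 240 lower). The libraries did not overlap for 46.4% of genes, against 10% by chance. After FUT6, CYR61, KLK12 and KRT4 the largest rises were the kallikrein KLK14 (2.79), DNASE1L2 (2.64), the lipoxygenase ALOX12B (2.55), GPNMB (2.31), heme oxygenase HMOX1 (2.27) and ZBED3 (2.23), as log2 changes. After DES the largest falls were PCP4 (-5.18), SH3BGR (-4.09), TPM1 (-3.81), SPARCL1 (-3.16), MAT2A (-3.099), NEXN (-2.77), LIMS2 (-2.77), PLEKHO1 (-2.76) and TPPP3 (-2.32), all but MAT2A and TPPP3 being lost without MC replicate 1 (adjusted p = 0.0882 for NEXN to 0.146 for LIMS2). Median-of-ratios scaling gave 1513 higher and 1319 lower genes. The count was 1676 without MC1, 1703 without MC2, 1801 without HC2, 1619 without HC3, and 1069 with the covariate.

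Smooth muscle markers averaged 7.06, 7.49 and 6.003 in the MC libraries and 3.07, 3.25 and 3.49 in the HC libraries, and 2.27 in LC3. In this list 0 of the 9 measured members rose, 2 fell and 7 did not pass the test (0 rises and 7 falls adjusted over the list alone), with SMTN (79.1 to 24.6 FPKM, log2 change -1.59) falling beside DES (median log2 -3.17, camera adjusted p = 0.0205, adjusted p = 0.778 with an estimated correlation). Of the genes with the largest falls, PCP4 was 126, 61.96 and 1.27 FPKM in LC1, LC2 and LC3, SH3BGR 28.8, 13.9 and 0.568, TPM1 99.1, 45.996 and 4.99, and NEXN 7.46, 3.52 and 0.258, so they varied with the smooth muscle markers inside LC. The calls of DES, SMTN, PCP4, SH3BGR, TPM1, SPARCL1, NEXN, LIMS2 and PLEKHO1 were lost without MC1, without MC2, without HC2 and without HC3. Over these fits adjusted p ran from 0.0769 for SPARCL1 to 0.146 for LIMS2. TPM1, NEXN and LIMS2 also share their locus with another gene. In the fibroblast list 0 of 10 members rose, 2 fell and 8 did not pass (0 and 2 over the list alone). Their median was -0.21, with camera adjusted p = 0.622, but 0.0223 with the covariate (median 0.69). In the endothelium list 0 of 9 members passed limma's test and 1 had an unadjusted p under 0.05 (0 rises and 0 falls adjusted over the list alone). Their median was -0.79, with camera adjusted p = 0.211, but 0.0343 without MC3. In the extracellular matrix list 2 of 26 members rose, 2 fell and 22 did not pass (1 and 1 over the list alone). Their median was -0.32, with camera adjusted p = 0.975, but 1.04e-05 with the covariate (median 0.58).

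In the cornified and differentiated layer list 6 of 28 members rose, 5 fell and 17 did not pass (10 and 5 over the list alone). Their median was 0.093, with camera adjusted p = 0.0347, adjusted p = 0.778 with an estimated correlation, and 0.2398 after quantile normalization, 0.135 without HC3 (median -0.066), 0.0585 without MC2 (median 0.016), 0.0567 without MC1, 0.0514 without HC1 and 0.272 with the covariate (median -0.028). ALOX12B, an enzyme of the cornified lipid barrier, rose from 0.266 ± 0.0763 FPKM in MC to 6.57 ± 1.88 FPKM in HC (log2 change 2.55 ± 0.17, adjusted p = 7.34e-06), KRT23 (16.4 to 66.5 FPKM, log2 change 1.94) rose, and TGM3 (552 to 268 FPKM, log2 change -1.03) fell. In the tight junction list 3 of 23 members rose, 5 fell and 15 did not pass (4 and 5 over the list alone). Their median was -0.13, with camera adjusted p = 0.975. CLDN4 rose from 280.4 ± 43.6 FPKM in MC to 435 ± 16.1 FPKM in HC (log2 change 0.64 ± 0.16, adjusted p = 0.0123), a call that was lost without MC replicate 2 and without HC replicate 3 (adjusted p = 0.0645 and 0.0524), and CGN (32.3 to 19.2 FPKM, log2 change -0.71) fell. CLDN1, OCLN and TJP1 did not pass. In the desmosome and adherens junction list 1 of 24 members rose, 5 fell and 18 did not pass (1 and 5 over the list alone). Their median was -0.081, the mean -0.075, direction of the set test up, with camera adjusted p = 0.824. DSG3 (339 to 179.98 FPKM, log2 change -0.90) fell. In the basal epithelial layer list 1 of 16 members rose, 4 fell and 11 did not pass (2 and 4 over the list alone). Their median was -0.033, with camera adjusted p = 0.988. ITGA3 (10.5 to 4.69 FPKM, log2 change -1.02) fell.

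In the oxidative stress, heat shock and unfolded protein list 2 of 49 members rose, 19 fell and 28 did not pass (2 and 22 over the list alone). Their median was -0.33, with camera adjusted p = 0.0264, adjusted p = 0.778 with an estimated correlation. HSPA5 fell from 282 ± 45.5 FPKM in MC to 101 ± 17.7 FPKM in HC (log2 change -1.48 ± 0.19, adjusted p = 3.66e-04), HSPA8 (762 to 365 FPKM, log2 change -1.07) and GCLC (15.2 to 5.31 FPKM, log2 change -1.35) fell, and HMOX1 rose from 14.9 ± 2.47 FPKM in MC to 76.7 ± 19.2 FPKM in HC (log2 change 2.27 ± 0.19, adjusted p = 4.01e-05). In the cell cycle and DNA replication list 1 of 49 members rose, 16 fell and 32 did not pass (1 and 16 over the list alone). Their median was -0.28, with camera adjusted p = 0.0141, adjusted p = 0.645 with an estimated correlation. PCNA (34.6 to 18.7 FPKM, log2 change -0.85) fell and CDKN1B (22.6 to 32.4 FPKM, log2 change 0.50) rose, while MKI67 (1.75 and 1.74 FPKM, adjusted p = 0.961) did not pass. In the cholesterol biosynthesis list 1 of 22 members rose, 7 fell and 14 did not pass (1 and 9 over the list alone). Their median was -0.29, with camera adjusted p = 0.204, but 0.00172 with the covariate (median -0.49). SQLE (29.99 to 12.9 FPKM, log2 change -1.17) fell. In the xenobiotic and retinoid metabolism list 8 of 26 members rose, 2 fell and 16 did not pass (9 and 2 over the list alone). Their median was 0.050, with camera adjusted p = 0.0224, adjusted p = 0.381 with an estimated correlation, and 0.112 after quantile normalization. ALDH1A3 (1.596 to 3.92 FPKM, log2 change 0.92) rose, and EPHX2 (31.3 to 15.4 FPKM, log2 change -0.99) fell. In the circadian clock list 5 of 18 members rose, 2 fell and 11 did not pass (5 and 2 over the list alone). Their median was 0.19, with camera adjusted p = 0.0538, but 0.0419 after quantile normalization and 0.0218 without a filter. NR1D1 (10.5 to 18.9 FPKM, log2 change 0.78) rose, and CRY1 (3.903 to 1.007 FPKM, log2 change -1.28) fell.

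In the ketogenesis and short-chain fatty acid activation list 0 of 18 members rose, 2 fell and 16 did not pass (0 and 1 over the list alone). Their median was 0.18, with camera adjusted p = 0.05598, but 0.0252 without a filter and 0.0239 without LC1. BDH1 (771 and 996 FPKM, adjusted p = 0.183) did not pass. In the short-chain fatty acid, bicarbonate and proton transport list 2 of 19 members rose, 1 fell and 16 did not pass (1 and 1 over the list alone). Their median was 0.085, with camera adjusted p = 0.21. SLC26A2 (24.002 to 48.5 FPKM, log2 change 0.99) rose, and SLC16A1 (297 and 413 FPKM, adjusted p = 0.0547), SLC26A3 and SLC9A3 did not pass. In the ion, urea, ammonia and water transport list 3 of 21 members rose, 4 fell and 14 did not pass (3 and 4 over the list alone). Their median was -0.14, with camera adjusted p = 0.984. The sodium pump subunit ATP1B1 (7.39 to 18.7 FPKM, log2 change 1.23) rose and the potassium channel KCNK1 (11.1 to 2.501 FPKM, log2 change -1.79) fell, the former sharing its locus with NME7. In the glucose and amino acid transport list 2 of 20 members rose, 6 fell and 12 did not pass (3 and 6 over the list alone). Their median was -0.13, the mean -0.13, direction of the set test up, with camera adjusted p = 0.997. SLC1A4 (1.56 to 7.78 FPKM, log2 change 1.78) rose, and SLC7A5 (7.31 to 2.91 FPKM, log2 change -1.07) and SLC5A1 (16.8 to 8.66 FPKM, log2 change -0.91) fell.

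In the tricarboxylic acid cycle list 3 of 21 members rose, 1 fell and 17 did not pass (5 and 1 over the list alone). Their median was 0.17, with camera adjusted p = 0.0287, adjusted p = 0.778 with an estimated correlation, and 0.167 after quantile normalization, 0.0593 without HC2, 0.0555 without MC2 and 0.517 with the covariate (median 0.086). IDH3A (33.3 to 16.7 FPKM, log2 change -0.95) fell. In the nuclear oxidative phosphorylation list 1 of 32 members rose, 2 fell and 29 did not pass (0 and 1 over the list alone). Their median was 0.17, with camera adjusted p = 0.0158, adjusted p = 0.778 with an estimated correlation, and 0.232 after quantile normalization and 0.901 with the covariate (median -0.13). In the glycolysis and lactate list 2 of 19 members rose, 0 fell and 17 did not pass (0 and 0 over the list alone). Their median was 0.083, with camera adjusted p = 0.233. In the fatty acid synthesis and storage list 4 of 21 members rose, 5 fell and 12 did not pass (4 and 5 over the list alone). Their median was -0.13, the mean -0.13, direction of the set test up, with camera adjusted p = 0.975. ACACA (3.81 to 1.86 FPKM, log2 change -0.74) fell. In the fatty acid oxidation and PPAR target list 4 of 30 members rose, 1 fell and 25 did not pass (4 and 1 over the list alone). Their median was -0.0081, the mean 0.073, direction of the set test up, with camera adjusted p = 0.182. ACAA1 (77.2 to 319 FPKM, log2 change 2.03) rose and FABP5 (1740 to 921 FPKM, log2 change -0.92) fell. Among the 68 ribosomal proteins 3 rose, 0 fell and 0 passed adjusted over the list alone (median log2 0.34, camera adjusted p = 9.31e-11, adjusted p = 0.778 with an estimated correlation).

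In the interferon response list 1 of 22 members rose, 6 fell and 15 did not pass (1 and 6 over the list alone). Their median was -0.31, with camera adjusted p = 0.168. ISG15 fell from 31.6 ± 4.72 FPKM in MC to 7.12 ± 1.31 FPKM in HC (log2 change -2.01 ± 0.16, adjusted p = 2.68e-05), and PARP9 (4.94 to 2.03 FPKM, log2 change -0.98) fell. In the antigen presentation list 3 of 11 members rose, 0 fell and 8 did not pass (3 and 0 over the list alone). Their median was 0.10, with camera adjusted p = 0.1399. TAP1 (2.98 to 5.56 FPKM, log2 change 0.72) was among the rises. In the Toll-like receptor and NF-kB list 4 of 35 members rose, 10 fell and 21 did not pass (4 and 10 over the list alone). Their median was -0.21, with camera adjusted p = 0.349. TLR2 fell from 9.22 ± 0.911 FPKM in MC to 5.61 ± 1.28 FPKM in HC (log2 change -0.64 ± 0.15, adjusted p = 0.00921), TRAF2 (24.3 to 10.9 FPKM, log2 change -1.103) fell and TLR5 (6.16 to 13.5 FPKM, log2 change 1.02) and FOS (16.7 to 42.5 FPKM, log2 change 1.29) rose. In the cytokine and chemokine list 5 of 27 members rose, 4 fell and 18 did not pass (6 and 6 over the list alone). Their median was 0.050, with camera adjusted p = 0.274. IL1R2 (83.1 to 155 FPKM, log2 change 0.89) rose, IL17RC (43.9 to 23.9 FPKM, log2 change -0.85) fell and IL1B (0.251 and 0.332 FPKM, adjusted p = 0.714) did not pass. In the epithelial host defence list 1 of 13 members rose, 5 fell and 7 did not pass (2 and 5 over the list alone). Their median was -0.30, with camera adjusted p = 0.3995. S100A14 (115 to 46.8 FPKM, log2 change -1.29) fell, and S100A8 (30.6 and 33.3 FPKM, adjusted p = 0.804) did not pass.

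In the apoptosis list 1 of 29 members rose, 0 fell and 28 did not pass (1 and 0 over the list alone). Their median was -0.10, the mean 0.026, direction of the set test up, with camera adjusted p = 0.411. The rise was in BBC3 (1.64 to 7.68 FPKM, log2 change 1.76). In the growth factor and IGF list 4 of 31 members rose, 5 fell and 22 did not pass (4 and 5 over the list alone). Their median was -0.040, the mean 0.018, direction of the set test up, with camera adjusted p = 0.386. IGFBP5 rose from 11.8 ± 1.55 FPKM in MC to 34.6 ± 6.302 FPKM in HC (log2 change 1.46 ± 0.18, adjusted p = 3.14e-04), and IGFBP6 (44.2 to 13.3 FPKM, log2 change -1.66) fell. In the macrophage and dendritic cell list 4 of 9 members rose, 0 fell and 5 did not pass (4 and 0 over the list alone). Their median was 0.39, with camera adjusted p = 0.0163, adjusted p = 0.425 with an estimated correlation. The complement gene C1QC (4.22 to 8.59 FPKM, log2 change 0.89) and the receptor chain FCER1G (1.42 to 3.13 FPKM, log2 change 0.76) rose. In the T and NK cell list 0 of 6 members rose, 1 fell and 5 did not pass (0 and 1 over the list alone). Their median was 0.025, the mean -0.020, direction of the set test up, with camera adjusted p = 0.6698. CD247 (3.07 to 1.61 FPKM, log2 change -0.65) fell. The small lists gave FFAR4 (14.8 to 5.499 FPKM, log2 change -1.29), which fell, CKM (3.35 to 5.48 FPKM, log2 change 0.57), which rose, and TNNT3 (98.4 and 166 FPKM, adjusted p = 0.137), JCHAIN (1.29 and 1.32 FPKM, adjusted p = 0.993) and CXCR2 (1.67 and 1.16 FPKM, adjusted p = 0.164), which did not pass, with the same calls adjusted over the list alone.

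Of 96 set tests over 32 lists, 32 passed camera with the preset correlation, and 1, the interferon response in HC minus LC, also passed with an estimated correlation. Leaving out 1 library kept 23 of the 32 in every fit.

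**Figure D4:**
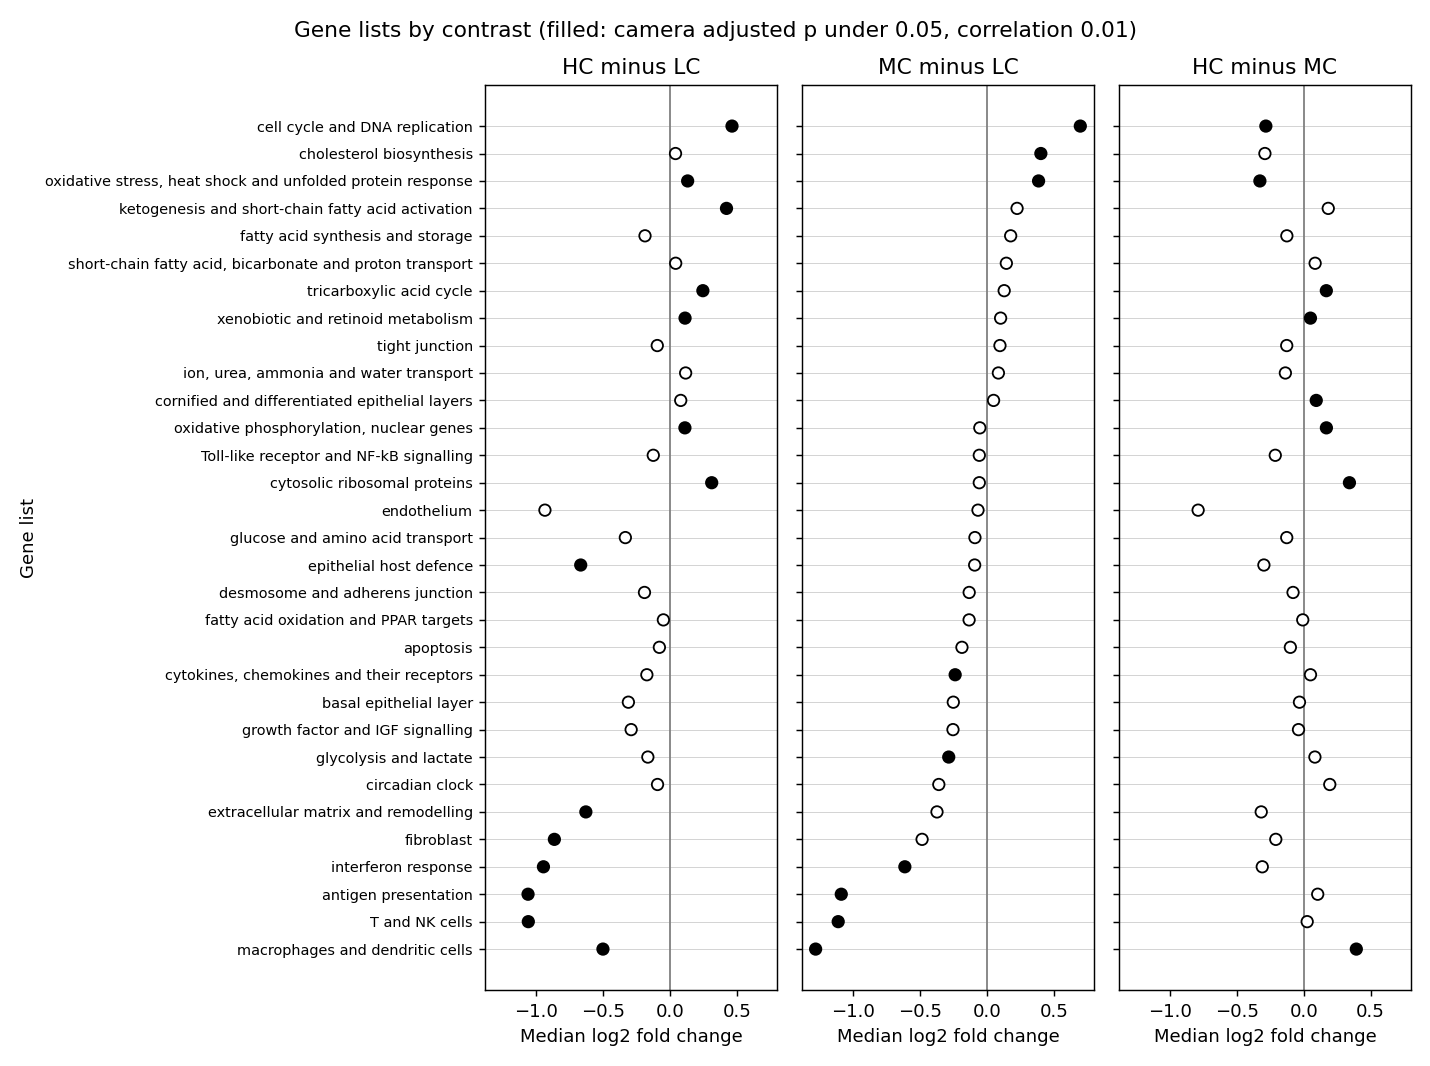
Median log2 fold change of each list in the 3 contrasts, for the lists with at least 5 tested members, with the smooth muscle list left out because its medians lie beyond the axis. Filled points passed camera with a preset correlation of 0.01, the cell cycle list lay highest in MC minus LC, and the immune lists lay below 0 in both contrasts with LC.

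HC and MC shared changes against LC, among them the rises of BDH1, SLC14A1 and MCM5 and the falls of S100A8, CD3E and PSMB8. In both contrasts 547 genes rose and 1035 fell, and 77 went opposite ways. Independent lists of the same sizes would share 148 rises and 348 falls. Log2 changes across genes had r = 0.576, against 0.494 with all diets simulated as unchanged, and a covariance of 0.168 against 0.0184. LC has only 3 libraries and was not split, so part of the excess may come from the shared controls. HC minus LC and HC minus MC, which share HC, had 218 common rises, 557 common falls and 220 opposite changes (independent lists 72.7 and 345), with r = 0.384 against 0.501 in simulated unchanged groups and a covariance of 0.0995 against 0.0188. MC minus LC and HC minus MC, which share MC with opposite signs, had 1565 opposite changes, 36 common rises and 70 common falls (independent lists 152 and 339.7), with r = -0.534 against -0.505 and a covariance of -0.151 against -0.01897. MAT2A, HSPA5 and KRT4 were among the opposite changes.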

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

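The tests in this part were chosen after the results were seen, except for the share of genes that followed muscle inside LC and the splits of the libraries. Genes with high values elsewhere were absent from all files of a diet. EEF1A1 (mean 2271 FPKM in the 6 other libraries), LOC106502455 (1944), LOC102177715 (25.1) and TMEM160 (43.3) were not listed in LC, and ND4 (14258) and ND4L (10797) were not listed in MC. LOC102182850 (26.3 FPKM) and LOC106501834 (14.1 FPKM) were listed in LC alone. At 10 FPKM or more, 6 genes were lost from the 3 trios of 1 diet and 0 from the 81 mixed trios, which argues against a loss library by library. Diet turning off ND4 and ND4L is argued against by the other mitochondrial genes, whose lowest ratio of MC over LC was 1.03 (ND2). Estimates lost for a diet as a whole in the authors' processing may be the cause. The HC files, laid out otherwise, leave a difference in their processing open. If each diet was processed as a unit, processing cannot be separated from diet in any contrast.

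Smooth muscle markers were far lower in HC than in MC. The LC libraries spanned 4.91 log2, 1.37 times the difference of 3.58 between MC and HC, which argues against diet as the whole cause and rests on LC3. A median of all genes of -0.10 argues against the authors' scaling. Muscle of the rumen wall left on some samples stays open and may be the source of the markers. It was not the source of most genes lower by at least 1 log2 in HC than in MC, since 4.62% of them (11 of 238) followed muscle inside LC, against 0.986% of all tested genes.

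S100A8 and S100A12 were higher in LC by more than 6 log2. The 15 T, NK, macrophage and dendritic cell markers had a median of -0.90 in HC minus LC (-1.91 to 1.68). They were too low in LC to test more leukocytes as the cause. Against more neutrophils, the highest of their genes in LC, CXCR2, reached 1.897 FPKM, with 6 of 8 list genes in the files. The median of all genes, -0.10, argues against scaling. An effect of diet on the epithelial cells was not tested and stays open.

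Each pair of diets allows 10 splits of its libraries, too few for a share under 0.05, and the real splits gave 2939, 3894 and 2917 genes and the others at most 0, so 1 split reached each count. For any difference among the diets 1 of 100 splits gave as many genes, the highest other being 1522 against 5274, which argues against chance.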

How the results depend on the processing

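The smooth muscle covariate, LC replicate 3 as the only LC library, leaving out 1 library for the lists and setting unlisted genes to 0 under the same filter were chosen after seeing the data. With a mean of at least 5 FPKM, where fewer genes are tested, 1674 genes changed in HC minus LC and 3375 differed among the diets. Library weights, 0.192 for LC1 and 7.59 for HC3, gave 5889 in HC minus LC, 6590 in HC minus MC and 8711 among the diets. At least 1 log2 left 579, 756 and 394 in HC minus LC, MC minus LC and HC minus MC. The covariate left 1069 in HC minus MC, and LC replicate 3 alone, with the spread taken from HC and MC, gave 1379 in HC minus LC and 2322 in MC minus LC. Leaving out 1 library gave 1769 (without HC3) to 2811 genes in HC minus LC and 2838 to 4043 in MC minus LC. It gave 1619 (without HC3) to 4066 (without LC1) in HC minus MC and 3988 to 5901 among the diets. HC minus MC was also 1676 without MC1, 1703 without MC2 and 1801 without HC2. Apart from the smaller number of genes or libraries, the cause was not tested. The other alternatives kept these counts within a factor of 1.5.

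Medians of called lists changed sign for nuclear oxidative phosphorylation in HC minus LC after quantile normalization (-0.0014), without LC replicate 1 (-0.084), with the covariate (-0.054) and with LC replicate 3 alone (-0.12), and in HC minus MC with the covariate (-0.13). They did so for the cornified layers in HC minus MC without HC3 (-0.066) and with the covariate (-0.028). Set tests also turned for extracellular matrix (median 0.58) and fibroblast (0.69) in HC minus MC with the covariate, and for smooth muscle (0.95) and extracellular matrix (-0.080) in HC minus LC with LC replicate 3 alone. The cause was not tested. Of 32 list calls 23 held after quantile normalization, 28 with a pseudocount of 0.1, 30 without a filter, 23 in every fit without 1 library and 20 with fry, which added 15. No named gene turned past the test. Some genes whose call 1 library ended were left out of the text, but not of these numbers: of 584 calls among 290 genes, 538 were kept in both other scalings, 452 in every fit without 1 library, 470 with the covariate, and 307 of 401 with LC replicate 3 alone.

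The replicate block gave 3751, 4613, 3871 and 6418 genes. It ended the list call of xenobiotic and retinoid metabolism in HC minus LC (adjusted p = 0.0589) and added those of endothelium in HC minus LC (adjusted p = 0.0275) and of extracellular matrix in MC minus LC (adjusted p = 0.0275). The labels give the numbers no meaning, and 6 of 9 pairs with the same number correlated above 0.1, the 3 pairs of number 1 at 0.2902 to 0.4496 among them. In all 3 of 9 libraries matched their own number best in both other diets, so a shared factor is not shown for every number. DESeq2 was not run because counts were not analysed here, and the unknown depth sets no limit of detection.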

Other observations

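The genes in this part were chosen after their values were seen. They were not tested as sets. In MC minus LC AMD1, which decarboxylates S-adenosylmethionine, rose from 10.1 ± 1.09 FPKM in LC to 45.96 ± 5.16 FPKM in MC (log2 change 2.08 ± 0.14, adjusted p = 1.96e-06) and SRM (8.62 to 17.96 FPKM, log2 change 0.98) rose. Spermine synthase SMS (12.98 to 8.79 FPKM, log2 change -0.52) and the polyamine acetyltransferase SAT1 (323 to 164 FPKM, log2 change -0.95) fell.

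In HC minus LC the transcription factor gene FOSB rose from 0.111 ± 0.113 FPKM in LC to 1.54 ± 0.176 FPKM in HC (log2 change 1.196 ± 0.14, adjusted p = 1.50e-04), and EGR1 (2.15 to 5.095 FPKM, log2 change 0.96) rose.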
